A study of Mus musculus with 6 samples.

How the data were processed

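The deposited matrices held counts of unique molecular identifiers (UMIs) per gene and barcode, and no other unit was provided by the authors. Per the labels, single nuclei were run on the 10x Genomics system, sequenced on a NovaSeq instrument and aligned to mm10. The aligner, the annotation and the way barcodes were called are not stated. No barcode had under 500 UMIs, and genes without counts were absent. The 6 libraries held 10115, 4225, 8571 and 6252 barcodes for vmPFC (sham 1, sham 2, GCI 1, GCI 2) and 10613 and 11057 for BLA (sham, GCI), with 41063296, 29712686, 60750745, 61848364, 37329686 and 37028330 UMIs.

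Barcodes under 500 genes (1396) or over 5% mitochondrial UMIs (35) were left out, then 3291 doublets called by Scrublet at an expected rate of 0.06. This kept 9090, 3907, 8013, 5965, 9425 and 9724 nuclei, with median UMIs of 2649, 5241, 6079, 8854, 3200 and 2898. Leiden clustering (resolution 1, 20 neighbours, 30 principal components, 2000 variable genes) and fixed marker genes named the classes, and clusters without a clear marker set were left unnamed and out of the class tests. The regions held 38009 and 36377 gene identifiers, and 33709 shared by both were used between regions. Positions come from GENCODE vM21 on mm10, which may differ from the annotation used upstream.

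In the vmPFC counts were summed by class and library, for classes with at least 20 nuclei in every library. Genes were tested by edgeR quasi-likelihood with TMM factors and filterByExpr, 2-sided, at an adjusted p (Benjamini-Hochberg) under 0.05. An endothelial test was planned but a library had only 13 nuclei, so it was not run. Kept nuclei of the 6 libraries held 34441361, 26192714, 53733454, 57382388, 33627357 and 32877396 UMIs. CPM are counts scaled to the effective library size. DESeq2 was the other test. Shares were compared by exact permutation, 2-sided. The 25 lists of genes and the marker lists were tested by limma camera at a correlation of 0.01, for lists with at least 5 members, and again with an estimated correlation. BLA ratios have exact conditional binomial intervals at 95%, and the median of a list was placed among 10000 random lists drawn in 20 bins of level. A ratio against 0 counts is a bound from a floor of 3 counts. The comparison between regions used all 6 libraries with a term for the operation.

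Genes were named by rule. In each vmPFC class these were the 4 largest changes each way that passed, with a mean of at least 10 CPM and both GCI libraries on the same side of both sham libraries, leaving out predicted, mitochondrial and sex-linked genes. Added to them were list members that passed, and the 2–4 members of highest level whether or not they passed. Where none passed, the 3 of smallest p were named. In the BLA the 3 highest and lowest ratios per class were named, given at least 50 counts in a library and an interval leaving out 1. Between regions it was the 5 largest each way, and not all are printed. These rules, the marker genes, the lists and most alternatives were fixed before the data were examined. The spiny neurons, the alternatives of another clustering start, mixed clusters, matched clusters, the crossed replicate term and genes enriched or highest in the class, the comparison of genes called in vmPFC with their BLA ratios, and Ptgds in oligodendrocytes were added afterwards. The clustering was computed again after results had been seen, so that any processor gives the same classes. Another start, as an alternative, put 45286 of the 46124 nuclei in the same class.

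Alternatives were other doublet, depth and filter settings, equal depth, leaving out each library, all 6 libraries together, a replicate term, replicate numbers crossed between operations as such a term, neurons drawn so that each cluster gave each library the same number of nuclei, another clustering start, and restriction to genes highest or enriched (4-fold) in the class. That restriction computed library totals and TMM factors again on the genes kept, so its changes are relative to those genes. Leaving out a vmPFC library leaves its group with a single library, so the spread then comes from the other group alone. Tests were checked on simulated data, where all 4-fold changes were recovered, and 34.0–95.6% of 2-fold changes with 1–11 false calls. The changes were placed only in genes of high count, and all genes of a class had the same dispersion. Genes of low count or wider spread were not covered, so the absence of a call does not exclude a 4-fold change. Correlations of deviations by replicate number ran from −0.208 to 0.136, so libraries were not paired. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.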

Results

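Nuclei from the ventromedial prefrontal cortex (vmPFC) and basolateral amygdala (BLA) of sham mice and of mice after global cerebral ischemia (GCI) were compared by deposited counts per gene. Per the labels, tissue was taken 7 days after the operation and 30 min after an acute swim stress. The vmPFC had 2 sham and 2 GCI libraries, whose labels do not say that they came from separate animals, so the replicates may be technical. The BLA had 1 library of each kind. After filtering, 46124 of 50833 deposited barcodes remained. Cell classes were named by their markers, so that astrocytes, for example, stand for astrocyte-like nuclei throughout.

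Excitatory neurons, which carry the vesicular glutamate transporter Slc17a7 and send the main output of the vmPFC, made up 46.0 ± 4.45% of nuclei in GCI and 15.6 ± 0.924% in sham (mean ± SD, n = 2 per group, 2.94-fold). Inhibitory neurons made up 10.9 ± 0.433% against 5.23 ± 2.05%, a ratio of 2.07. Glial classes lay the other way, with astrocytes at 7.54 ± 2.24% against 16.3 ± 4.83%, oligodendrocytes at 5.65 ± 0.0181% against 11.2 ± 3.54%, oligodendrocyte precursors at 4.09 ± 0.290% against 11.1 ± 3.43%, and microglia at 5.41 ± 0.737% against 10.1 ± 1.08%. The libraries of the groups did not overlap in any of these 6 classes, save that microglia did among nuclei of 1000 or more genes, with a difference of −1.81 percentage points against −4.72 (oligodendrocytes −3.42 there). Without sham replicate 1 the differences shrank from −8.73 to −5.31 points in astrocytes, from −5.53 to −3.02 in oligodendrocytes and from −7.04 to −4.62 in oligodendrocyte precursors. Spiny neurons, marked by striatal-type genes, made up 7.21 ± 1.25% in GCI and 9.93 ± 6.63% in sham, and without sham replicate 2 the difference turned to 1.98 percentage points in favour of GCI. Taken as shares of neurons, which leave out the unnamed clusters, spiny neurons differed more, at 11.3% in GCI and 30.4% in sham. Inhibitory neurons were 17% of neurons in GCI and 16.8% in sham (17.7% and 19.5% with another start of the clustering), astrocytes were 30.8% and 32.2% of glia, while oligodendrocytes (23.6% against 22.1%) and microglia (22.4% against 20.6%) changed sides. Oligodendrocyte precursors stayed lower, at 17% of glia against 22%. Excitatory neurons were 71.7% of neurons against 52.9%. With 2 libraries per group the smallest 2-sided exact permutation p is 0.333, the value for each of the 6 classes whose libraries did not overlap, so the design cannot reach 0.05.

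**Figure D1:**
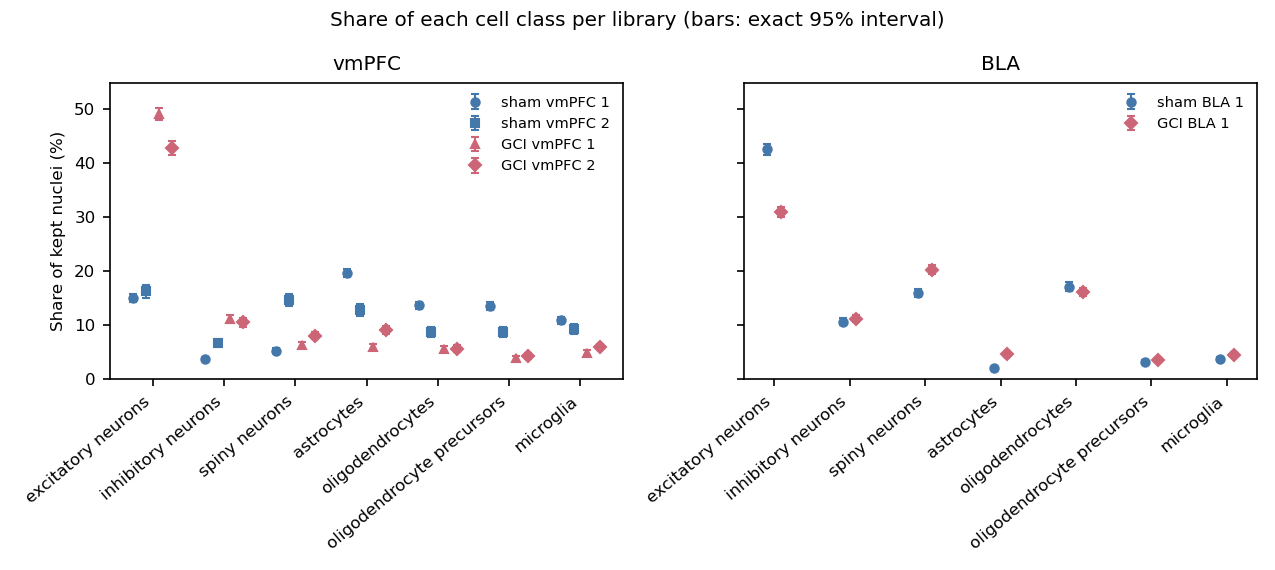
Share of nuclei in each cell class, by library. Each point is 1 library of the vmPFC or BLA, coloured by operation.

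Neurons of the vmPFC gave 0 called genes by edgeR in each of the 3 classes. This hung on the settings, since edgeR did call genes in all 3 without the low-count filter. It also did in inhibitory neurons with a crossed replicate term, and these counts are given with the alternatives below. In excitatory neurons 1163 of 19827 genes had an unadjusted p under 0.05 and DESeq2 called 21. The inhibitory neurons had 930 of 14145 and 15, and the spiny neurons had 654 of 14059 and 5. The genes of smallest p, none of which passed, began in each class with Ptgds, which encodes a prostaglandin D synthase made by meningeal and oligodendrocyte-lineage cells (ENSMUSG00000015090, mm10 chromosome 2, 25466709–25470046). Its GCI level was 0.218 of sham in excitatory neurons (log2 −2.20, SE 0.25, adjusted p = 0.30, n = 2 per group), 0.219 in inhibitory neurons (log2 −2.19, SE 0.27, adjusted p = 0.13) and 0.194 in spiny neurons (log2 −2.37, SE 0.29, adjusted p = 0.18). Over all nuclei Ptgds was at 22.4 and 21.8 CPM (counts scaled to library size) in the GCI libraries and 137 and 120 in the sham libraries. Clusters with meningeal markers, which make Ptgds, held 0.324% and 0.168% of GCI and 1.496% and 1.587% of sham nuclei. In excitatory neurons the LIM-domain gene Lmo3 was at 160 ± 0.585 CPM in GCI and 293 ± 7.95 in sham (adjusted p = 0.79), and Plpp4 at 15 ± 5.89 and 46.7 ± 2.40 (adjusted p = 0.79). In inhibitory neurons the delta opioid receptor gene Oprd1 was at 37.6 ± 4.84 CPM against 11.7 ± 0.0117 (adjusted p = 0.13) and versican, Vcan, at 21.7 ± 2.66 against 61.3 ± 9.31 (adjusted p = 0.13). Leaving out GCI replicate 1 gave 67 called genes in excitatory and 75 in inhibitory neurons. Leaving out GCI replicate 2 gave 25, 113 and 92 in excitatory, inhibitory and spiny neurons. The classes were not alike in their makeup, since among excitatory neurons a Rorb cluster held 18.8% of them in GCI replicate 1, 2.27% in GCI replicate 2, and 0.955% and 1.26% in the sham libraries. Among inhibitory neurons a cluster held 70.2% and 68.4% in GCI and 39.0% and 59.8% in sham.

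Gene groups of glia stood lower in GCI neurons, beside a higher level of ribosomal genes that hung on a single library. In excitatory neurons the astrocyte homeostasis list had a mean log2 change of −0.69 (21 members, 0 called over all genes and 9 over the list alone, adjusted p = 1.2e-11), which was adjusted p = 0.51 with an estimated correlation. The homeostatic microglia list was at −0.77 (15 members, 0 and 6 called, adjusted p = 1.1e-10; adjusted p = 0.47 with an estimated correlation). The same list was at −0.75 in inhibitory neurons (13 members, 0 and 5 called, adjusted p = 1.5e-08; adjusted p = 0.40 with an estimated correlation). Astrocyte homeostasis lost its shift in excitatory neurons without sham replicate 1 (−0.04, adjusted p = 0.20). The cytosolic ribosomal proteins list was at 0.33 in excitatory neurons (56 members, 0 called either way, adjusted p = 0.0012; adjusted p = 0.79 with an estimated correlation) and turned to −0.38 without GCI replicate 2. The glucocorticoid response list was at −0.39 in excitatory (24 members, 0 called either way, adjusted p = 0.0016; adjusted p = 0.56 with an estimated correlation) and −0.39 in inhibitory neurons (18 members, 0 called either way, adjusted p = 0.0034; adjusted p = 0.48 with an estimated correlation), and was at 0.00 and −0.12 without sham replicate 1. The immediate early genes list, which reports recent firing, did not move in excitatory neurons (30 members, mean −0.06, 0 called, adjusted p = 0.67). In inhibitory neurons it was at −0.23 (25 members, 0 called either way, adjusted p = 0.015; adjusted p = 0.64 with an estimated correlation), with Egr1 at −0.59, Nr4a1 at −0.52, Per1 at −0.21 and Homer1 at 0.13, none of which passed, and the list turned to 0.05 without GCI replicate 2.

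Astrocytes of GCI vmPFC carried more transcripts of genes such as Grin2a and Syt1 and fewer of Ptgds and Nkx6-2. Tmem178, a membrane protein gene of calcium signalling (ENSMUSG00000024245, mm10 chromosome 17, 80944632–81001816), rose 4.16-fold (log2 2.05, SE 0.24, adjusted p = 0.0058, n = 2 per group), from 11.3 ± 1.93 to 48.4 ± 3.19 CPM. Grin2a, an NMDA receptor subunit gene (ENSMUSG00000059003, mm10 chromosome 16, 9567898–9995560), rose 2.30-fold (log2 1.20, SE 0.16, adjusted p = 0.0080), from 185 ± 28.5 to 429 ± 25.1 CPM. Ptgds fell to 0.253 of sham (log2 −1.98, SE 0.22, adjusted p = 0.0058), from 133 ± 33.7 to 34.2 ± 3.41 CPM. In all, edgeR called 241 genes higher and 42 lower of 12282, DESeq2 called 250, and 0 were called without sham replicate 1 and 1249 without GCI replicate 1, against 138 without sham replicate 2 and 4 with called doublets kept. Adamts18 (3.98-fold, adjusted p = 0.032), Trnp1 (3.58-fold, adjusted p = 0.024) and the actin-binding Synpo (3.35-fold, adjusted p = 0.023) rose. Nkx6-2, a homeobox gene of the oligodendrocyte lineage (ENSMUSG00000041309, mm10 chromosome 7, 139579376–139582797), fell to 0.120 of sham (adjusted p = 0.012), Olig1 to 0.317 (adjusted p = 0.023) and Pdgfra to 0.308 (adjusted p = 0.041). Olig1 and Pdgfra are markers of oligodendrocyte precursors, which were scarcer in GCI vmPFC, so carried-over RNA cannot be told apart for them.

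The glutamate receptors and scaffolds list rose in astrocytes, with 13 of 37 members called higher over all genes and 20 over the list alone (mean log2 0.55, adjusted p = 1.3e-14), but adjusted p = 0.30 with an estimated correlation. Among them Grin2a rose, Dlg2 rose 1.64-fold (adjusted p = 0.043) and Camk2a rose 2.89-fold (adjusted p = 0.047). The voltage-gated sodium and calcium channels list had 9 of 24 members called higher (17 over the list alone, mean 0.67, adjusted p = 4.5e-15; adjusted p = 0.30 with an estimated correlation). The synaptic vesicle and release list had 8 of 38 (17 over the list alone, mean 0.53, adjusted p = 2.3e-12; adjusted p = 0.40 with an estimated correlation), Syt1 rising 1.98-fold and Snap25 1.87-fold. Of the glucocorticoid response list 3 of 22 members fell (5 over the list alone, mean −0.53, adjusted p = 1.2e-07; adjusted p = 0.51 with an estimated correlation). These were the metallothioneins Mt1 (0.593 of sham, adjusted p = 0.048) and Mt2 (0.483, adjusted p = 0.048) and Arrdc2 (0.301, adjusted p = 0.047), while Nr3c2 and Mertk did not pass. The astrocyte homeostasis list stood lower, with 1 of 21 members called (12 over the list alone, mean −0.43, camera adjusted p = 1.4e-11, and 0.40 with an estimated correlation). Fitted on genes enriched in the class alone, the list was at −0.08 relative to those genes (camera adjusted p = 0.18). Kcnj16 fell to 0.429 of sham (adjusted p = 0.023), Gabrg1 to 0.577 (adjusted p = 0.027) and Vegfa to 0.522 (adjusted p = 0.023), whereas the glutamate transporter Slc1a2 and Gpc5 did not pass. The reactive astrocyte list stood at a mean of −0.42 with 0 of 11 members called either way (camera adjusted p = 0.0097, and 0.51 with an estimated correlation). It was at −0.04 without sham replicate 1. Markers of other cells moved with the operation in these nuclei, those of the excitatory neuron by a mean log2 of 1.19 (5 of 9 called higher) and those of the microglia by −0.96 (2 of 11 called lower).

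In oligodendrocytes of GCI vmPFC transcripts of Mmp24 and Grin2a rose, and those of Olig2 and Insig1 fell. Mmp24, a membrane metalloproteinase gene (ENSMUSG00000027612, mm10 chromosome 2, 155775342–155818366), rose 4.95-fold (log2 2.31, SE 0.44, adjusted p = 0.024, n = 2 per group), from 4.41 ± 0.447 to 22.6 ± 6.79 CPM. Olig2, which specifies the lineage (ENSMUSG00000039830, mm10 chromosome 16, 91225457–91228677), fell to 0.305 of sham (log2 −1.71, SE 0.32, adjusted p = 0.023), from 38.1 ± 6.19 to 11.8 ± 1.53 CPM. The sterol regulator Insig1 fell to 0.306 (log2 −1.71, SE 0.35, adjusted p = 0.029), from 28.7 ± 0.122 to 8.71 ± 0.999 CPM. In all, edgeR called 198 genes higher and 34 lower of 10027 and DESeq2 called 198, with 161 without sham replicate 1, 761 without GCI replicate 1 and 431 without GCI replicate 2. With all 6 libraries edgeR called 1, with a replicate term 422, and with called doublets kept 6. Mkx (4.16-fold, adjusted p = 0.023) and Tmem145 (4.13-fold, adjusted p = 0.039) rose. The GABA transporter Slc6a11 (0.372 of sham, adjusted p = 0.041) and the connexin Gja1 (0.392, adjusted p = 0.041) fell. Gja1 is a marker of astrocytes, which were scarcer in GCI vmPFC, so carried-over RNA cannot be told apart for it.

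In the same cells 11 of 37 members of the glutamate receptors and scaffolds list were called higher (22 over the list alone, mean log2 0.59, adjusted p = 1.3e-14), with adjusted p = 0.30 with an estimated correlation. Grin2a rose 2.36-fold (adjusted p = 0.0083) and Cacng3 3.09-fold (adjusted p = 0.0095). The potassium channels list had 9 of 36 called higher (20 over the list alone, mean 0.64, adjusted p = 1.1e-13; adjusted p = 0.40 with an estimated correlation), Kcnip4 rising 1.78-fold. The synaptic vesicle and release list had 8 of 38 (18 over the list alone, mean 0.54, adjusted p = 1.7e-12; adjusted p = 0.40 with an estimated correlation), with Syt1 rising 1.80-fold and Sv2b 2.48-fold. The myelin and oligodendrocyte maturation list stood lower, with 1 of 25 members called (7 over the list alone, mean −0.38, camera adjusted p = 9.5e-10, and 0.36 with an estimated correlation). Fitted on genes enriched in the class alone, the list turned to 0.03 relative to those genes. Cldn11 fell from 575 ± 58.0 to 323 ± 59.3 CPM (0.562 of sham, adjusted p = 0.032), while Mbp did not pass. The glucocorticoid response list had 2 of 21 members called lower, over all genes and over the list alone (mean −0.53, adjusted p = 1.9e-05; adjusted p = 0.51 with an estimated correlation), and was at −0.12 (adjusted p = 0.090) without sham replicate 1. These were Errfi1 (0.483 of sham, adjusted p = 0.046) and Arrdc2 (0.430, adjusted p = 0.034). The astrocyte homeostasis list had 4 of 20 members lower (13 over the list alone, mean −0.68, adjusted p = 5.2e-10; adjusted p = 0.47 with an estimated correlation), Slc1a3 among them. Markers of the excitatory neuron moved by a mean log2 of 1.16 (4 of 9 called higher) and those of the microglia by −1.03 (2 called lower). Ptgds, chosen after the values had been seen, fell to 0.533 of sham (adjusted p = 0.024).

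In oligodendrocyte precursors of GCI vmPFC Pdzrn3 and Grin2a rose, and Ptgds and Mag fell. Pdzrn3, a ubiquitin ligase gene, rose 3.24-fold (log2 1.70, SE 0.26, adjusted p = 0.0067, n = 2 per group), from 35.3 ± 9.12 to 120 ± 43.6 CPM. Ptgds fell to 0.242 of sham (log2 −2.05, SE 0.21, adjusted p = 0.00083), from 109 ± 9.79 to 26.3 ± 3.04 CPM. Mag, a gene of mature myelin, fell to 0.293 (log2 −1.77, SE 0.34, adjusted p = 0.026), from 31.7 ± 5.26 to 9.26 ± 3.31 CPM. In all, edgeR called 87 genes higher and 26 lower of 10663 and DESeq2 called 129, with 766 without GCI replicate 1, 305 without GCI replicate 2 and 92 without sham replicate 2. With all 6 libraries edgeR called 44, with a replicate term 313, and with called doublets kept 13. Fbxl16 (3.66-fold, adjusted p = 0.029) and Dkk3 (3.28-fold, adjusted p = 0.017) rose. The glutamate receptors and scaffolds list had 9 of 37 members higher (20 over the list alone, mean log2 0.38, adjusted p = 1e-07; adjusted p = 0.40 with an estimated correlation), with Grin2a rising 2.27-fold (adjusted p = 0.00091). Syt1 rose 1.97-fold (adjusted p = 0.00088) and Sv2b 2.86-fold (adjusted p = 0.0023). The myelin and oligodendrocyte maturation list had 2 of 21 lower (8 over the list alone, mean −0.53, adjusted p = 1.5e-06; adjusted p = 0.40 with an estimated correlation). These included Mag, while Enpp2 did not pass. The mitochondrially encoded transcripts list stood at a mean of 0.97 with 0 of 6 members called over all genes and 4 over the list alone (camera adjusted p = 0.0019, and 0.59 with an estimated correlation). Its members mt-Cytb and mt-Nd1 did not pass, and the list turned to −0.21 without GCI replicate 2. Markers of the excitatory neuron moved by a mean log2 of 1.40 (4 of 7 called higher) and those of the microglia by −1.21 (1 of 10 called lower).

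In microglia of GCI vmPFC Fcrls and Pilra fell, and Galnt9 and Grin2a rose. Fcrls, a receptor gene of resting microglia (ENSMUSG00000015852, mm10 chromosome 3, 87250758–87263738), fell to 0.468 of sham (log2 −1.10, SE 0.21, adjusted p = 0.044, n = 2 per group), from 208 ± 36.3 to 98.1 ± 18.2 CPM. The inhibitory immune receptor gene Pilra (ENSMUSG00000046245, mm10 chromosome 5, 137821952–137836281) fell to 0.221 (log2 −2.18, SE 0.42, adjusted p = 0.045), from 30.5 ± 6.18 to 6.65 ± 2.35 CPM. Galnt9, a glycosyltransferase gene of neurons (ENSMUSG00000033316, mm10 chromosome 5, 110544355–110621380), rose 6.19-fold (log2 2.63, SE 0.45, adjusted p = 0.038), from 6.45 ± 5.59 to 45.7 ± 5.88 CPM. In all, edgeR called 111 genes higher and 19 lower of 10145 and DESeq2 called 260. Without sham replicate 1 the count was 0, likewise without sham replicate 2, and it was 1282 without GCI replicate 1 and 761 without GCI replicate 2. It was 1 with a replicate term, 3 with all 6 libraries and 1 with called doublets kept. Another start of the clustering, which kept all 2903 microglia of the 6 libraries and added others to reach 3111, gave 466. Adding the unnamed clusters of mixed microglial and other markers to the microglia gave 466 as well. Tmem178 (3.78-fold, adjusted p = 0.032), March11 (3.62-fold, adjusted p = 0.045) and Adamtsl1 (3.35-fold, adjusted p = 0.037) also rose, and Pdgfra (0.220 of sham, adjusted p = 0.041), Ptgds (0.272, adjusted p = 0.029) and Afap1l1 (0.294, adjusted p = 0.040) fell. Pdgfra is a marker of oligodendrocyte precursors, and Ptgds and Afap1l1 are top genes of the clusters with meningeal markers. Such nuclei were scarcer in GCI vmPFC, so RNA carried over from them cannot be told apart here.

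The homeostatic microglia list in microglia had 2 of 15 members lower over all genes and 14 over the list alone (mean log2 −0.69, adjusted p = 5.8e-15), with adjusted p = 0.30 with an estimated correlation. P2ry12, at 386 ± 34.6 against 635 ± 37.7 CPM (adjusted p = 0.059), Csf1r, at 571 ± 14 against 853 ± 21.3 (adjusted p = 0.081), and Cx3cr1 (adjusted p = 0.072) did not pass. Fitted on the genes highest in this class alone, the list was at −0.53 relative to those genes. There 0 members were called over those genes and 12 over the list alone (camera adjusted p = 9.9e-16, and 0.48 with an estimated correlation). Fitted on enriched genes alone, the list was at −0.38 relative to them (13 members, camera adjusted p = 6.5e-07, and 0.29 with an estimated correlation). The activated microglia list did not move, with 0 of 13 called and a median of −0.19 beside a mean of −0.03 (adjusted p = 0.35), and its members Apoe and Ctsd did not pass. Of the glutamate receptors and scaffolds list 7 of 37 were called higher (25 over the list alone, mean 0.79, adjusted p = 2.5e-22; adjusted p = 0.30 with an estimated correlation), Grin2a rising 2.35-fold (adjusted p = 0.029) and Dlg2 and Dlgap1 not passing. Of the synaptic vesicle and release list 3 of 38 were called higher (19 over the list alone, mean 0.62, adjusted p = 3.1e-13; adjusted p = 0.47 with an estimated correlation), Syt1 rising 1.90-fold (adjusted p = 0.037). The glucocorticoid response list was at −0.35 (17 members, 0 called either way, adjusted p = 0.018; adjusted p = 0.59 with an estimated correlation), Fkbp5 not passing, and was at −0.09 (adjusted p = 0.34) without sham replicate 1. Markers of the excitatory neuron moved in these microglia by a mean log2 of 0.98, with 2 of 8 called higher.

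**Figure D2:**
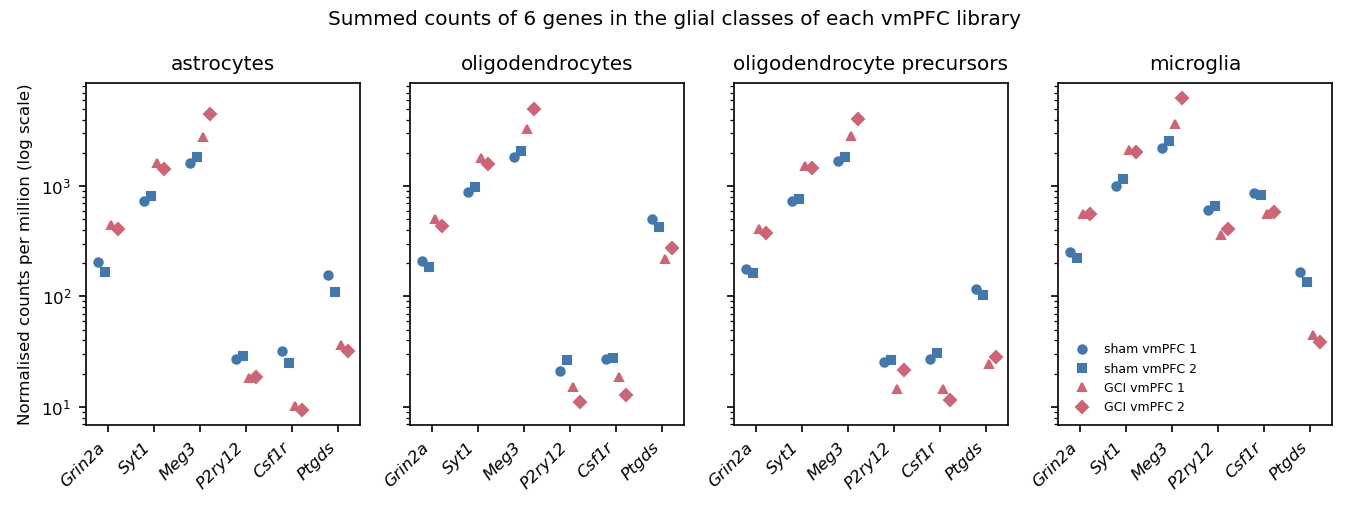
Level of 6 genes in the 4 glial classes of the vmPFC. Each point is 1 library, in CPM of the summed counts of the class, on a log axis.

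Across the 7 vmPFC classes, synaptic and channel gene lists stood higher in glia, with members called. Glial lists stood lower in neurons, where no gene was called over all genes. Of 173 pairs of a list and a class, 44 moved up and 39 down at a fixed correlation of 0.01, and 0 moved by the limma test with an estimated correlation, where 20 had an unadjusted p under 0.05. Of the 637 calls higher in glia, 635 (99.7%) had a higher level in excitatory neurons than in the class where they were called. A gene called in several classes counts once in each. Of the 121 calls lower in glia, 119 had a lower level in excitatory neurons than in the class. The same shares over all tested genes were not computed. Fitted on the genes highest in each class alone, and so relative to them, 3 of 40 pairs moved up and 9 down. With an estimated correlation 0 moved, and 1 had an unadjusted p under 0.05. In 15 pairs the median, mean and test differed in sign, as for GABA receptors and GABA handling in astrocytes, whose median log2 was −0.02 and mean 0.14. The cytosolic ribosomal proteins list changed sign in each class that it was called in once GCI replicate 2 was left out, as in astrocytes, from 0.53 to −0.50, and in oligodendrocyte precursors, from 0.57 to −0.73. Rpl41 and Rps21, its members of highest level there, did not pass.

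**Figure D3:**
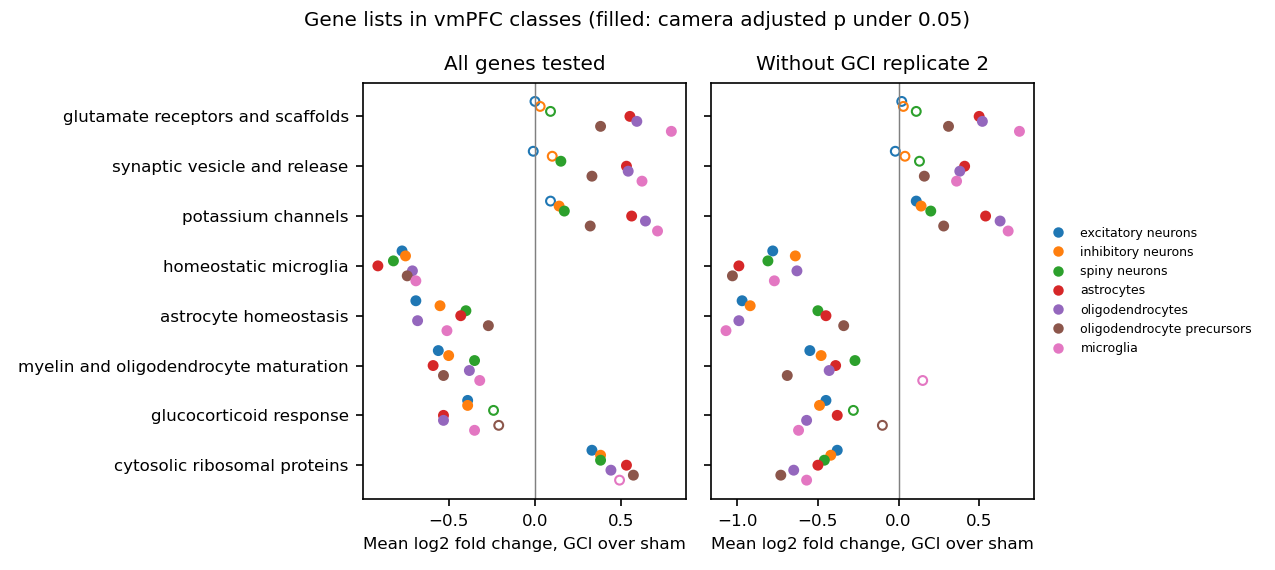
Mean log2 change of 8 gene lists in the 7 vmPFC classes. The left panel holds all libraries and the right panel leaves out GCI replicate 2.

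In the BLA, each operation had 1 library, so values are given without a test and their exact 95% intervals cover counting error only. Excitatory neurons made up 30.9% (30.0–31.9) of nuclei in GCI and 42.6% (41.6–43.6) in sham. Astrocytes, which take up synaptic glutamate, made up 4.60% (4.19–5.03) against 2.05% (1.77–2.35), and microglia 4.55% (4.14–4.98) against 3.8% (3.42–4.20). Spiny neurons made up 20.3% (19.5–21.1) against 15.9% (15.2–16.7), inhibitory neurons 11.2% (10.6–11.8) against 10.6% (10.0–11.3), oligodendrocytes 16.1% (15.4–16.9) against 17.2% (16.4–17.9) and oligodendrocyte precursors 3.57% (3.21–3.96) against 3.18% (2.84–3.56). As a share of glia, astrocytes differed by 7.76 percentage points and oligodendrocytes by −9.64. Within the inhibitory neurons a single cluster held 47.6% in GCI and 23.7% in sham.

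Prss22, Amhr2 and Cartpt had the largest differences in BLA neurons, the former pair in glia of the same libraries as well. Prss22, which encodes a serine protease (ENSMUSG00000045027, mm10 chromosome 17, 23993534–23998100), was at 9.37 CPM in GCI and 0.543 in sham excitatory neurons, a log2 ratio of 4.11 (3.23 to 5.14). It was at 12.1 and 0.355 in spiny neurons (log2 5.09, 3.20 to 8.16) and at 54 and 0 counts in inhibitory neurons, at least 4.03 on the log2 scale from a floor of 3 counts, with a lower 95% limit of 3.68. Its level in the glia of that GCI library was 18.4 CPM in astrocytes, 15.6 in oligodendrocytes and 28.1 in microglia, so the difference was not confined to neurons. Amhr2, a hormone receptor gene (ENSMUSG00000023047, mm10 chromosome 15, 102445367–102454633), was at 1.18 and 11.1 CPM in excitatory neurons, a log2 ratio of −3.24 (−4.02 to −2.54), and at 18.3 CPM in oligodendrocytes of the sham library. In the same neurons Gpr139 (log2 1.72, 1.03 to 2.45) was higher, and the large-conductance channel subunit Kcnmb3 (log2 −1.94, −3.02 to −0.99) and Ddit4l (log2 −1.85, −2.83 to −0.97) were lower. Spiny neurons had more of the neuropeptide gene Cartpt (ENSMUSG00000021647, mm10 chromosome 13, 99898489–99901091), at 12.4 against 0.887 CPM (log2 3.8, 2.53 to 5.46). They had less of the cannabinoid receptor gene Cnr1 (ENSMUSG00000044288, mm10 chromosome 4, 33924593–33948831), at 35 against 108 CPM (log2 −1.63, −1.84 to −1.41). Inhibitory neurons had less Crhbp, whose product binds corticotropin-releasing hormone (ENSMUSG00000021680, mm10 chromosome 13, 95431371–95444924), at 7.45 against 22.3 CPM (log2 −1.58, −2.22 to −0.97), and more Dlk1 (log2 2.53, 1.44 to 3.82) and Thbs3 (log2 1.80, 1.28 to 2.35). The immediate early genes list had a median log2 ratio of −0.22 in excitatory neurons (31 members, percentile 0 of 10000 random lists matched by level), where 3 had intervals above 0 and 11 below. Fos was at 2.49 CPM against 6.07 (log2 −1.29, −1.85 to −0.75), Per1 at −0.50 and Nr4a1 at −0.33, while Npas4 was at 0.36 (0.10 to 0.61). Subtype markers of the same neurons differed too, with medians of −0.28 for L2/3 intratelencephalic excitatory (percentile 0.3), −0.35 for L4/5 intratelencephalic excitatory (percentile 0.1), 0.46 for L6 corticothalamic excitatory and 0.44 for inhibitory neuron markers (both at percentile 100). In inhibitory neurons the immediate early genes list lay the other way, at a median of 0.20 (27 members, percentile 96.5, 2 above and 1 below). There the neuropeptides and trophic factors list was at −0.24 (24 members, percentile 0, 4 above and 9 below). Markers of intercalated or central amygdala inhibitory neurons were at 0.78 in that class (percentile 100), those of Pvalb inhibitory at −0.40, Sst inhibitory at −0.36 and Vip inhibitory at −0.41.

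BLA oligodendrocytes had less Sgk1 and Gli2 in GCI, and microglia less Pde4b. In oligodendrocytes the glucocorticoid response list had a median log2 ratio of −0.31 (22 members, percentile 0.1, 0 above and 7 below), and in microglia it was level, at −0.04 (17 members, percentile 44, 1 above and 0 below). Sgk1, a kinase gene switched on by glucocorticoids, was at 253 CPM in GCI and 397 in sham (log2 −0.65, −0.81 to −0.49), Arrdc2 at −0.84 and Errfi1 at −0.69. Magt1, a magnesium transport gene, was at 248 against 114 CPM in oligodendrocytes (log2 1.12, 0.89 to 1.35) and at 116 against 34.5 in oligodendrocyte precursors (log2 1.74, 0.98 to 2.58), and over all nuclei of the BLA at 67.5 against 26.9. Gli2 was at 8.02 against 30.5 CPM in oligodendrocytes, and Ltbp1 at 112 against 236 in oligodendrocyte precursors. In astrocytes Plcl2 was at 98.5 against 20.4 CPM (log2 2.27, 0.97 to 3.95) and the hypoxia-inducible factor gene Hif3a at 127 against 306 (log2 −1.27, −1.75 to −0.79). In microglia Fcrls was at 117 against 49.7 CPM (log2 1.24, 0.40 to 2.15), and the phosphodiesterase gene Pde4b was at 79.7 against 236 (log2 −1.57, −2.19 to −0.96). Pde4b stood at 0.26 with called doublets kept. The homeostatic microglia list was level in microglia, at a median of −0.03 (percentile 37.7). The glutamate receptors and scaffolds list was at −0.28 in oligodendrocytes (37 members, percentile 0, 7 above and 10 below) and −0.31 in microglia (26 members, percentile 1.1), but at 0.12 in oligodendrocyte precursors (35 members, percentile 98.7) and 0.10 in astrocytes (34 members, percentile 86.8). In the same oligodendrocytes excitatory neuron markers were at −0.50 (percentile 1.7) and inhibitory neuron markers at −0.48 (percentile 0.3), and in astrocytes oligodendrocyte markers were at −1.15 (percentile 0). Of the genes called higher in vmPFC oligodendrocytes, 192 had enough BLA counts, and their median BLA log2 ratio was −0.38 against −0.09 for all genes. The 89 such genes of microglia were at −0.51 against −0.03, the 182 of astrocytes at −0.15 against −0.02 and the 70 of oligodendrocyte precursors at −0.09 against −0.03. In the BLA at 1000 or more genes per nucleus, the median ratio of excitatory neuron markers moved from 0.02 to 1.88 in astrocytes and from −0.04 to 4.43 in microglia. These values rest on few nuclei and counts, since the main BLA clusters of these classes had median UMIs of only 1199 and 875.

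Between the regions, Xirp2 was higher and Piezo2 and Nr2f2 were lower in BLA excitatory neurons, with the operation accounted for. In excitatory neurons the muscle-type gene Xirp2 was at 59.2 CPM in the BLA and 1.67 ± 0.366 in the vmPFC (log2 5.14, SE 0.19, adjusted p = 6e-07, n = 2 and n = 4), and Olfr277-ps1 at 33.2 and 0.472 ± 0.201 (log2 6.09, SE 0.23, adjusted p = 5.9e-07). Piezo2, a mechanically gated channel gene (ENSMUSG00000041482, mm10 chromosome 18, 63010213–63387183), was at 0.859 and 36.0 ± 13.6 CPM (log2 −5.39, SE 0.50, adjusted p = 3.2e-05). The nuclear receptor gene Nr2f2 was at 0.843 and 30.4 ± 7.60 (log2 −5.18, SE 0.34, adjusted p = 4.2e-06). In all, edgeR called 5099 genes higher and 3351 lower in BLA excitatory neurons of 20426, 2940 and 1949 in inhibitory neurons of 15453, and 1619 and 1421 in astrocytes of 12797. The total of 8450 in excitatory neurons was 4403 without the sham and 4633 without the GCI library of the BLA, that of 4889 in inhibitory neurons was 3057 and 2226, and that of 3040 in astrocytes was 916 without the GCI library. These calls compare largely different clusters, since the main clusters of BLA excitatory neurons held almost no vmPFC nuclei, and of BLA astrocytes 188 and 437 lay in a separate cluster against 5 and 10 in that of the vmPFC. Muc15, Gpr171 and Trpv6 were also higher in BLA excitatory neurons, and Mfge8, Ptpn14 and Rerg lower. In inhibitory neurons the glycosyltransferase gene Galnt2 (ENSMUSG00000089704, mm10 chromosome 8, 124231391–124345724) was at 39.1 and 0.202 ± 0.237 CPM (log2 6.91, SE 0.36, adjusted p = 2.9e-08). Over all nuclei of the BLA and vmPFC, Galnt2 was at 31.2 and 0.295 CPM and Olfr277-ps1 at 30.5 and 0.492. Muc15 was at 62.6 and 1.41 there and Gpr171 at 25.6 and 1.05, so these differences were not particular to the class named. Xirp2, at 31.5 and 0.937, was below its BLA level of 59.2 in excitatory neurons. The files of the regions named 1318 gene identifiers differently. Differences in annotation or processing between these files can thus not be told from the region, for these genes or for the numbers called. The kynurenine pathway gene Kmo (log2 4.41) and Gse1 (log2 4.31, SE 0.17, adjusted p = 9e-09) were higher, and Gpr37l1 (log2 −4.26, SE 0.51, adjusted p = 3.2e-05) was lower. Kmo and Gse1 were higher over all BLA nuclei too, at 22 and 134 CPM against 1.43 and 10.8. Over all vmPFC nuclei Gpr37l1 was at 35.8 CPM and Mfge8 at 39.2, above their levels in these neurons. RNA carried over from other cells can thus not be told apart for this pair. In astrocytes Prss56 (ENSMUSG00000036480, mm10 chromosome 1, 87183313–87188405) was at 35.8 and 1.20 ± 1.47 CPM (log2 5.14, SE 0.67, adjusted p = 2.9e-05), and Veph1 and Enkur were higher. There Bdnf, which had 0 counts in the BLA, was at least 3.90-fold lower, Rasl10b at least 4.43-fold and Cnnm1 at least 6.77-fold. The BLA astrocytes held only 844283 UMIs. Over all vmPFC nuclei Bdnf was at 25.2 and Cnnm1 at 77 CPM, above their 15.9 and 27.8 in vmPFC astrocytes. For these genes too, carried-over RNA cannot be told apart. Rasl10b was at 13.2 over all vmPFC nuclei and 16.9 ± 18.4 in vmPFC astrocytes.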

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

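BLA shares differed between the libraries in percentage points by −11.7 for excitatory neurons, 2.55 for astrocytes and 3.82 for unnamed clusters (GCI less sham), while the vmPFC excitatory and astrocyte shares lay the opposite way. The difference between regions was not tested, and 1 library per operation cannot tell operation from dissection.

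Some genes called higher in vmPFC glia lay lower in the BLA, and others such as Adamts18 in astrocytes, at 1.23, did not. The BLA log2 ratios of those lower were −0.30, −0.60 and −0.42 for Meg3 in astrocytes, oligodendrocytes and oligodendrocyte precursors, −0.93 and −1.34 for Grin2a in oligodendrocytes and microglia, and −0.50 for Kcnip4 and −0.41 for Syt1 in oligodendrocytes. Fcrls in microglia fell in the vmPFC and was at 1.24 in the BLA. None of these differences between regions was tested.

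Some unnamed clusters were uneven among libraries. A cluster with Foxp2, Tshz1 and Meis2 was 0.44% of the GCI and 0.159% of the sham BLA library. In the vmPFC it lay the opposite way, at 6.77% and 9.37% of sham against 3.92% and 5.53% of GCI nuclei. A pair of clusters with meningeal markers was scarcer in GCI vmPFC, at 0.176 and 0.15 of the sham share. Another with microglial and neuronal markers was 0.58% of GCI vmPFC nuclei, and 0.286% and 0.23% of the sham libraries. A cluster with haemoglobin and neuroblast genes was 4.34% of the GCI and 2.25% of the sham BLA library, and a further unnamed cluster 1.48% and 0.34%. Their differences were not tested.

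Some genes were high in a single library. Prss22 was at 11.2 CPM over all nuclei of the GCI BLA library and 2.96 in GCI vmPFC replicate 1. Amhr2 was at 11 in the sham BLA library, Catspere1 at 24.1 in sham vmPFC replicate 1, and the haemoglobin genes Hba-a1 and Hbb-bs at 12 and 18.2 in the sham BLA library. Prss22 and Amhr2 were high in neurons and glia alike of their library, and Magt1 over all nuclei was at 67.5 in the GCI and 26.9 in the sham BLA library. Whether this came from the operation or from the animals was not tested.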

How the results depend on the processing

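Counts of called vmPFC genes moved most. Leaving out a library is given as lowest–highest, and the cause was not tested. Such counts rest on the spread of the other group alone, since a single library is left in the group.

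Excitatory neurons (0 called): no filter 235, DESeq2 21, replicate term 3, leaving out 0–67, clusters matched 1, crossed replicate term 3. Inhibitory neurons (0): no filter 109, DESeq2 15, replicate term 1, equal depth 5, leaving out 0–113, another start 3, clusters matched 1, crossed replicate term 83. Spiny neurons (0): no filter 101, DESeq2 5, replicate term 2, equal depth 2, leaving out 2–92.

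Astrocytes (283): no filter 679, doublets kept 4, leaving out 0–1249, genes enriched in or highest in the class 0 and 0. Oligodendrocytes (232): no filter 446, replicate term 422, all 6 libraries 1, doublets kept 6, leaving out 161–761, enriched 0, highest 0. Oligodendrocyte precursors (113): no filter 350, replicate term 313, all 6 libraries 44, doublets kept 13, equal depth 203, leaving out 92–766, enriched 0, highest 7. Microglia (130): no filter 646, DESeq2 260, replicate term 1, all 6 libraries 3, doublets kept 1, leaving out 0–1282, another start 466, mixed clusters included 466, enriched 0, highest 0.

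Of 173 pairs of list and class 83 moved, and 0 with an estimated correlation. Where fewer could be tested, 12 of 40 moved among genes highest in the class and 1 of 4 among enriched genes. Leaving out a library gave the following ranges, each turned without GCI replicate 2 except that of disease-associated oligodendrocyte. Oxidative phosphorylation, nuclear encoded ran from −0.19 to 0.52 in excitatory neurons, −0.17 to 0.56 in inhibitory neurons and −0.28 to 0.76 in oligodendrocyte precursors. Cytosolic ribosomal proteins ran from −0.38 to 0.77 in excitatory, −0.42 to 0.91 in inhibitory and −0.46 to 0.78 in spiny neurons, −0.50 to 0.97 in astrocytes, −0.65 to 0.92 in oligodendrocytes and −0.73 to 1.03 in precursors. Immediate early genes in inhibitory neurons ran from −0.41 to 0.07, with 0.05 without GCI replicate 2. Mitochondrially encoded transcripts in precursors ran from −0.21 to 1.66, and myelin and oligodendrocyte maturation in microglia from −0.83 to 0.15 (0.25 with another start, 0.24 with mixed clusters). Potassium channels in inhibitory neurons went to −0.05 among genes highest in the class, and myelin and oligodendrocyte maturation in oligodendrocytes to 0.03 among enriched genes. Disease-associated oligodendrocyte in oligodendrocytes ran from −0.59 to 0.26, the latter without sham replicate 1.

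Genes that turned: Homer1 in inhibitory neurons −0.20 (without GCI 1, up to 0.41), Slc1a2 in astrocytes 0.18 and 0.07 (enriched, highest), Mbp in oligodendrocytes 0.13 (enriched), Zbtb16 in oligodendrocytes 0.17 (without sham 1, down to −1.54), Rps21 in precursors −0.32 (without GCI 2, up to 1.66), and Apoe in microglia 0.03 (1000 genes), 0.12 (without sham 1) and 0.07 (without GCI 2). In the BLA these were Cep152 in microglia −0.43 (1000 genes), and Pde4b 0.26 and Sgcz 0.01 (doublets kept). Values marked enriched or highest are relative to those genes of the class alone.

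Share differences in percentage points turned in the vmPFC for spiny neurons (leaving out gave −7.40 to 1.98, the latter without sham replicate 2), oligodendrocytes of glia (1.51) and microglia of glia (1.82). Inhibitory neurons of neurons went from 0.18 to −1.82 with another start. In the BLA they moved for excitatory neurons from −11.7 to −14.05 (1000 genes), inhibitory neurons from 0.55 to 2.53 (of neurons), spiny neurons from 4.42 to 6.65 and 9.55, astrocytes from 2.55 to 0.81 and 7.76, and oligodendrocytes from −1.05 to 0.81 and −9.64.

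BLA excitatory neuron markers at 1000 genes, which few of these nuclei reached, moved from 0.02 to 1.88 in astrocytes and from −0.04 to 4.43 in microglia. Genes called between regions ran, on leaving out a library, from 4403 (without sham BLA; 4633 without GCI BLA) to 8913 for excitatory neurons (8450 with all), from 2226 (without GCI BLA; 3057 without sham BLA) to 4844 for inhibitory neurons (4889), and from 916 (without GCI BLA) to 2944 for astrocytes (3040, and 1334 at 1000 genes). The endothelial test, planned for the vmPFC, could not be run under any setting.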

Other observations

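In GCI vmPFC Grin2a and Syt1 rose in all 4 glial classes, among other genes, and the genes that fell included Ptgds, Olig2 and Fcrls. Ptgds encodes a prostaglandin D synthase of the meninges and oligodendrocyte lineage, Fcrls is a gene of resting microglia, Grin2a is a gene of glutamate synapses and Syt1 one of synaptic vesicles. In the BLA Grin2a lay lower in GCI oligodendrocytes and microglia. Whether genes that fell in vmPFC glia, such as Ptgds, reflect RNA carried over from scarcer cells was not tested.

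For the neuronal genes in glia, the first test was written before the values were seen and the others were chosen after. Of genes called higher, 84.6% (539 of 637) also stood higher over all nuclei of both GCI libraries. So did 24.5% of all genes of at least 10 CPM, a floor that was not set for the called genes. But genes of excitatory neurons must stand higher where such neurons are more abundant, so this cannot tell carried-over RNA from other causes. RNA of excitatory neurons in glial droplets could still account for the rise, since in oligodendrocytes and microglia of the BLA, whose share of excitatory neurons was lower in GCI, 79.4% of such genes (223 of 281) lay below the median, though only 56% did in BLA astrocytes and 58.6% in precursors. Thinning to equal totals gave 858 calls beside 758, so the number of calls did not hang on unequal totals of the libraries. This count holds both directions and does not show which of the genes stayed, and depth per nucleus was not matched. Altered transcription in the glia themselves could not be told apart, with 7 of 9174 genes highest in the class called, or 0.076%, against 758 of 43117 over all genes, or 1.76%, and the explanation stays open.

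For the larger excitatory share in GCI vmPFC, all tests were chosen after the result was seen. Leaving out low-depth nuclei kept the ratio at 2.64, among nuclei with 1000 or more genes. This cut cannot show nuclei lost before barcodes were called. Nor does it match depth, with median UMIs of 2649 and 5241 in sham and 6079 and 8854 in GCI libraries. Loss of low-depth nuclei is thus not excluded. A different piece of cortex may have been taken, since the ratio of GCI to sham differed 17.2-fold among 6 excitatory clusters, from 1.71 to 29.39. The highest ratio came from a cluster that held 9.25% of GCI replicate 1 and 0.972% of GCI replicate 2, and the others of these reached 6.59, so this explanation stays open. Ischemia itself cannot be told from it at an exact permutation p of 0.333.

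For the fall of homeostatic genes in microglia, all tests were chosen after the result was seen. Dilution by RNA of neurons could lower them, though the list stood at −0.38 relative to other genes enriched in microglia, so this test cannot tell. Activation of the microglia might lower them too, and the activated microglia list, at −0.09 relative to other genes highest in microglia, cannot tell either. A dissociation of these would need the RNA of empty droplets, which was not used here.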
